A study of Homo sapiens and Mus musculus with 16 samples.

How the data were processed

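RNA sequencing libraries of A1847, PC3 and MyC-CaP;p53KO cells were grouped by line and treatment from the sample titles, with the replicate number given there. The authors deposited TPM values, read shares scaled by gene length, for the human lines together and for the mouse line. Per the labels, libraries were made with poly(A) selection and a directional kit. Per the submitters' processing notes, BWA 0.7.17, SAMtools 1.16.1, featureCounts, Subread 1.6.2 and the builds T2T-CHM13 and GRCm39 were used, with no roles given. The strand setting of the counting is not given in the sources used here, so genes that overlap or lie antisense to another are uncertain. The tables give gene symbols without coordinates, and the build of the reference at hand may differ from that of the authors, so no coordinates are given. For the human lines 17322 genes are listed, with 2 further columns that match no sample used, 1 of them headed as a further A1847 DMSO sample and 1 a mean. The labels used here do not list that sample, so it was not used as another control, and A1847 DMSO has 2 libraries. For the mouse line 26418 entries are listed, of which 1 without a gene name (at most 1.36 TPM) was left out. Mitochondrially encoded mRNAs and some human genes of the lists, among them CGAS and STING1, were not analysed here.

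A gene's deposited TPM values in a library are whole multiples of the value of a read, up to gene length. Whole read numbers were recovered for 100.0% of the genes above 0 (14116 human and 13343 mouse, within a tolerance of 0.0001 of a whole number). A gene above 0 in a single library always gives a whole number, so for such genes this share checks nothing. The smallest numbers that fit were taken, so recovered reads are lower bounds. Their sums were 1205095 and 587994 for A1847 DMSO, 186586, 2622998 and 999644 for A1847 GNS561, 2074627 and 1848383 for PC3 DMSO, 1999919, 237678 and 2222882 for PC3 GNS561, 770547, 786780 and 711373 for MyC-CaP;p53KO DMSO, and 3087783, 478182 and 450270 for MyC-CaP;p53KO GNS561. In a library of 186586 reads a gene of few TPM has few reads or none, so a value of 0 there is weak evidence.

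Tests used limma 3.58.1 in R 4.3.3 (version 1.17.8 of data.table) on log2(TPM + 1), so that changes of low genes are understated, with a mean per group, eBayes with a variance trend and Benjamini-Hochberg adjustment at 0.05. Human genes needed at least 1 TPM in 2 libraries and mouse genes in 3. Both human lines shared a fit, and the difference of their responses was a contrast in it. The tables of the 2 species were tested separately, and human against mouse effects were not tested. The design, gene lists, rule for named genes and most repeats with other settings were fixed before the data were examined. Fits on 9 human libraries, without the library labelled A1847 GNS561 replicate 3, are also a planned leave-one-out, but describing the human lines from them was decided after the data were examined, as was voom on recovered reads (limma, same genes).

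The 28 gene lists covered interferon-stimulated genes, cGAS-STING pathway components, NF-kB targets with cytokines and chemokines, class I antigen presentation, checkpoint and immune recognition ligands, cholesterol biosynthesis, fatty acid synthesis, LXR targets, lysosomal hydrolases and membrane proteins, the vacuolar ATPase, the autophagy and TFEB network, integrated stress response (ATF4) targets, the unfolded protein response, NRF2 targets, metallothioneins and zinc handling, iron handling, hypoxia, heat shock, immediate early genes, p53 targets, S phase, G2/M and mitosis, depalmitoylating enzymes, mitochondrially encoded mRNAs, and markers of epithelial cells, fibroblasts, leukocytes and endothelium. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a line. Camera with an estimated correlation also rests on the residual degrees of freedom (5 with 9 human libraries, 6 with 10, 4 in mouse). The preset version does not, so a larger p-value with the estimated correlation need not come from correlation alone. Members were counted over all genes tested and adjusted over the list alone. Some genes, such as FTH1 and CALR, belong to more than 1 theme.

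Named genes were, per line, the 6 largest rises and 6 largest falls past the threshold with a proper symbol and at least 5 TPM in the higher group, up to 3 called members of each list, and always PPT1, CGAS, STING1, TBK1, IRF3, IFNB1, CCL5, CXCL10, ISG15, IFIT1, TFEB and MYC, with the 4 largest in each direction for the difference of the human lines and 5 in each direction for all 3 lines. Of these, MYC stood at 62.3 ± 12.0 and 78.2 ± 1.09 TPM in A1847 (adjusted p = 0.416, 0.817 in voom), 266 ± 0.555 and 205 ± 9.93 TPM in PC3 (0.299, 0.00678 in voom) and 953 ± 66.6 and 861 ± 66.7 TPM in the mouse line (Myc; 0.430, 0.0226 in voom). TFEB did not pass in any line. Genes were matched between species by symbol, ignoring case, and expected overlaps are those of independent lists. The other settings were pseudocounts of 0.1 and 5, no filter and a filter of at least 5 TPM, median-ratio and quantile scaling, no variance trend, robust variance, a replicate block, each human line alone, an added limit of 1 on the absolute log2 change, and leaving out each library. Where that left a group with 1 library, the lone library was assumed to vary like the other groups.

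The procedure was tested on simulated reads with the depths of these libraries, 100 genes changed 2-fold and 100 changed 4-fold. At a dispersion of 0.01 it recovered 54% of the 4-fold changes in A1847 and 51% in PC3 (12095 genes) and 79% in MyC-CaP;p53KO (11236 genes), and 6%, 12% and 31% of the 2-fold changes. At a dispersion of 0.05 it recovered 1%, 18% and 59% of the 4-fold changes (12107 human and 11207 mouse genes). No recovered gene had the wrong sign. At a dispersion of 0.01, unchanged genes made up 7 of 67 calls in A1847, 2 of 65 in PC3 and 8 of 119 in MyC-CaP;p53KO, and with voom 7 of 121, 17 of 159 and 6 of 166. A set of 30 genes raised 1.5-fold was found in each simulation, and 0 to 5 of 50 random sets passed an unadjusted 0.05. The human simulation used 9 libraries, and simulated genes were drawn independently of each other. It therefore cannot tell how the preset correlation performs when list members are correlated. Summaries and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Bootstrap intervals are of 95% from 2000 draws over genes.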

Results

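Messenger RNA was measured by sequencing in 3 cancer cell lines after 24 h with GNS561 at 5 µM or with DMSO alone. GNS561 is a small molecule described as an inhibitor of PPT1, a lysosomal enzyme that removes palmitate from proteins. The series title concerns PPT1 and signaling by STING, the adaptor of the cytosolic DNA sensor cGAS. A1847 is a human ovarian cancer line, PC3 a human prostate cancer line, and MyC-CaP;p53KO a mouse prostate cancer line driven by Myc and labelled as a p53 knockout. The human lines had 2 DMSO and 3 GNS561 libraries each and the mouse line 3 and 3, so 16 libraries were used. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Values were deposited as TPM, a read share scaled by gene length. Reads recovered from their steps, which are lower bounds, numbered 186586 to 2622998 in A1847, 237678 to 2222882 in PC3 and 450270 to 3087783 in MyC-CaP;p53KO. Genes with low TPM therefore rest on few reads in the shallowest libraries.

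The library labelled A1847 GNS561 replicate 3 did not resemble the other 4 A1847 libraries. Over 14516 gene symbols shared by the human and mouse tables, its Spearman correlation across genes was at most 0.759 with another A1847 library and at least 0.865 with each mouse library. The other 4 A1847 libraries correlated at 0.922 or more with each other (genes are not independent replicates). PAX8, a transcription factor of ovarian cancer cells, stood at 0 TPM in it against 98.3 to 214 TPM in the other A1847 libraries. ALDH1A1, a retinal dehydrogenase, stood at 11490 TPM against 0 to 0.528, and MYC at 1887 TPM against 53.9 to 79.0. The mouse libraries held 3713 to 6151 and 794 to 1030 TPM of the same symbols. With all 10 human libraries, limma called 0 of 12129 genes changed in A1847 (708 at an unadjusted p under 0.05, 0 with voom on recovered reads). It called 4 in PC3 and 0 for the difference between the lines (340 unadjusted, 0 with voom). The accounts of A1847 and PC3 that follow use the 9 human libraries without it, a choice made after the data were examined. Gene counts and list results with all 10 libraries follow with the tests, and other 10-library values only where stated.

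**Figure D1:**
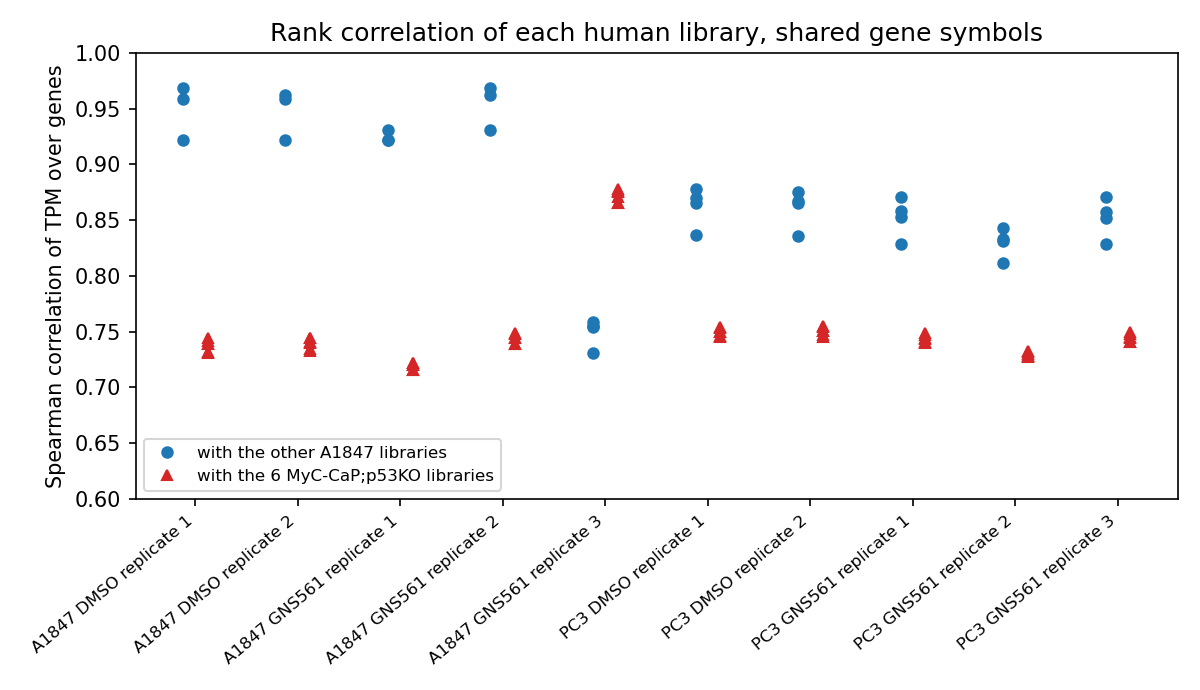
Spearman correlation of TPM across 14516 shared gene symbols (y axis) between each human library (x axis) and other A1847 libraries (circles) or the 6 MyC-CaP;p53KO libraries (triangles). Circles of the other libraries leave out their correlation with the library labelled A1847 GNS561 replicate 3. The library labelled A1847 GNS561 replicate 3 is the one whose triangles (0.865 and above) lie above its circles (0.759 and below).

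The first comparison asked what GNS561 changed in A1847 cells. Of 24 measured genes of cholesterol synthesis 14 rose and 0 fell over all genes tested, and 21 rose adjusted over the list alone. Their median log2 change was 1.45, against -0.01 with all 10 libraries (adjusted p = 0.459). HMGCS1, which makes the precursor of mevalonate, rose from 84.0 ± 6.99 to 401 ± 36.4 TPM (SD, n = 2 and 2; adjusted p = 0.00347 by limma). INSIG1, a sterol sensor of the endoplasmic reticulum, rose from 35.6 ± 3.33 to 238 ± 84.4 TPM, and FDPS from 98.4 ± 5.00 to 413 ± 162 TPM. Of 15 genes of fatty acid synthesis 3 rose and 9 rose adjusted over the list alone. SCD, the stearoyl-CoA desaturase, rose from 129 ± 24.9 to 596 ± 27.8 TPM, ACSS2 from 17.4 ± 0.890 to 94.3 ± 24.9 TPM and FADS2 from 56.9 ± 5.12 to 171 ± 20.4 TPM. HMOX1, the heme oxygenase, rose 8.16-fold, from 21.9 ± 0.0157 to 179 ± 15.2 TPM (adjusted p = 0.000344).

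Of 31 integrated stress response (ATF4) targets in A1847 5 rose and 17 rose adjusted over the list alone. TRIB3, a pseudokinase induced by ATF4, rose from 13.9 ± 2.20 to 102 ± 24.4 TPM, DDIT4, an inhibitor of mTORC1, from 20.2 ± 0.878 to 124 ± 0.524 TPM. DDIT3, the transcription factor CHOP, rose from 21.5 ± 4.74 to 91.2 ± 17.2 TPM. Of 24 unfolded protein response genes 4 rose and 12 rose adjusted over the list alone. Among the 4 were the endoplasmic reticulum chaperones HYOU1 (114 ± 3.59 to 306 ± 42.2 TPM) and HSP90B1 (1058 ± 50.7 to 1822 ± 99.1 TPM) and the coat protein gene SEC24D (36.3 ± 1.79 to 106 ± 13.4 TPM). Of 25 NRF2 targets, genes of the antioxidant response, 4 rose, and 11 rose and 1 fell adjusted over the list alone. HMOX1 and the ferritin genes FTH1 (1142 ± 68.1 to 2494 ± 97.5 TPM) and FTL were among them. Of 48 lysosomal genes 4 rose and 14 rose adjusted over the list alone. They included the sialidase NEU1 (48.5 ± 6.97 to 182 ± 28.6 TPM), CTSA, the protease that protects it, and the cholesterol carrier NPC2. Of 38 autophagy genes 2 rose and 9 rose adjusted over the list alone. The 2 were the autophagy receptor SQSTM1 (395 ± 18.7 to 1498 ± 350 TPM) and GABARAP (192 ± 5.74 to 313 ± 9.91 TPM; voom adjusted p = 0.0876).

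Of 24 NF-kB targets, cytokines and chemokines in A1847, 2 rose and 9 rose adjusted over the list alone. The cytokine IL1A was listed at 0 in both DMSO libraries and reached 24.2 ± 2.96 TPM, and the adhesion molecule ICAM1 rose from 137 ± 30.7 to 349 ± 16 TPM. Mean log2 values of the NF-kB list stood 0.38 above the DMSO mean in GNS561 replicate 1 and 1.25 in replicate 2, and those of the lysosomal list 0.17 and 0.63. Of 35 genes of G2/M and mitosis 3 fell and 9 fell adjusted over the list alone (median log2 change -0.58). CDC20, an activator of the anaphase-promoting complex, fell from 320 ± 6.56 to 154 ± 21.9 TPM, BIRC5 from 313 ± 9.67 to 158 ± 15.3 TPM and CCNB1, cyclin B1, from 927 ± 179 to 493 ± 5.70 TPM. Among 21 heat shock genes 1 fell and 3 fell adjusted over the list alone, with HSP90AA1 at 3107 ± 104 and 2034 ± 241 TPM. Among 14 epithelial markers 1 fell, the keratin KRT7 (1956 ± 184 to 851 ± 45.4 TPM), while 1 rose and 3 fell adjusted over the list alone. The other large falls were NDUFB7, LDHA, the lactate dehydrogenase (1462 ± 80.2 to 742 ± 73.7 TPM), and TACO1. Other large rises were BEX2 (11 ± 3.28 to 117 ± 30.1 TPM), NIPAL4, TEKT2 and SNORD42A. TEKT2 rested on 10 reads and SNORD42A on 2, and neither passed in voom. PPT1 stood at 224 ± 64.5 and 221 ± 3.23 TPM (adjusted p = 1.00), TBK1 at 26.3 ± 0.680 and 57.3 ± 23.2 TPM (0.177, 0.387 in voom) and IRF3 at 32.3 ± 8.23 and 28.0 ± 4.003 TPM (0.782). No interferon-stimulated gene passed among 36 (median log2 change 0.02, and -0.95 with all 10 libraries). ISG15 stood at 154 and 38.2 TPM in DMSO and 73.1 and 57.4 TPM in GNS561 and IFIT1 at 10.2 ± 5.61 and 4.76 ± 2.02 TPM. CCL5, CXCL10 and IFNB1 were listed at 0 in all 4 libraries.

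In these 4 A1847 libraries limma called 93 of 12030 genes, 78 higher and 15 lower, and voom on recovered reads 342 higher and 285 lower. By camera with a preset correlation of 0.01, 12 of 27 lists passed, and 4 of them held with an estimated correlation. These were cholesterol synthesis (adjusted p = 1.72e-21 and 0.0305), fatty acid synthesis (2.79e-09 and 0.0422), the unfolded protein response (1.09e-10 and 0.0373) and NRF2 targets (2.54e-05 and 0.0373). The other 8 passed only with the preset one. They included integrated stress response (1.02e-10; adjusted p = 0.0735 with an estimated correlation), G2/M and mitosis (1.15e-12; adjusted p = 0.0572 with an estimated correlation). The lysosomal (2.71e-06), autophagy (0.000125), NF-kB (1.60e-05), iron handling (0.000253), heat shock (0.000253) and epithelial lists (0.0200) each had adjusted p = 0.108 with an estimated correlation. The count moved to 30 and 40 without A1847 DMSO replicates 1 and 2, to 19 and 1023 without A1847 GNS561 replicates 1 and 2. It moved to 36 without either PC3 DMSO library, to 29 and 28 without PC3 GNS561 replicates 1 and 3. Other settings gave 57 (44 higher, 13 lower) with median-ratio scaling, 33 without a variance trend and 2 with A1847 fitted alone. The NF-kB and heat shock lists no longer passed without GNS561 replicate 2, nor the epithelial list with either rescaling. Epithelial markers were lower only in GNS561 replicate 1, the shallowest library (-0.53, against 0.05 in replicate 2), where fibroblast (-0.78 against 0.11) and leukocyte markers (-1.56 against 0.17) were lower too. With all 10 libraries 0 genes and 4 lists passed. These were the unfolded protein response (1.43e-13; adjusted p = 0.00442 with an estimated correlation), integrated stress response (1.83e-08; adjusted p = 0.127 with an estimated correlation) and autophagy (0.000176; adjusted p = 0.238 with an estimated correlation) upward and G2/M downward (1.21e-08; adjusted p = 0.268 with an estimated correlation). Fatty acid synthesis (adjusted p = 0.118), NRF2 targets (0.145), lysosomal genes (0.348) and NF-kB targets (0.459) did not pass with all 10. The median of all genes lay at -0.174, moving to -0.131 and 0.06 with median-ratio and quantile scaling.

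The second comparison asked the same in PC3 cells. AGR2, a protein disulfide isomerase of the endoplasmic reticulum, rose 32.6-fold, from 19.2 ± 3.09 to 626 ± 52.5 TPM (SD, n = 2 and 3; adjusted p = 9.09e-05 by limma, 0.00398 with all 10 libraries). Of 24 unfolded protein response genes 9 rose and 14 rose adjusted over the list alone (median log2 change 0.85). The chaperones HSP90B1 rose from 900 ± 50.2 to 3697 ± 192 TPM and HSPA5 from 626 ± 17 to 2474 ± 110 TPM (adjusted p = 3.55e-05 each, 0.0149 with all 10 libraries). DNAJB9 and HERPUD1, a factor of protein degradation at the endoplasmic reticulum, rose 4.69-fold and 4.18-fold. Of 31 integrated stress response targets 9 rose, and 21 rose and 1 fell adjusted over the list alone. Among the 9 were TRIB3 (94.0 ± 23.3 to 351 ± 25.7 TPM), CTH, a cysteine-forming enzyme (32.0 ± 9.35 to 124 ± 24.6 TPM), and NUPR1 (8.12 ± 1.14 to 38.1 ± 7.39 TPM). Of 35 genes of G2/M and mitosis 19 fell and all 35 fell adjusted over the list alone (median log2 change -1.47). TOP2A, the mitotic topoisomerase, fell from 191 ± 5.88 to 41.9 ± 13.7 TPM, the kinase gene AURKB from 179 ± 29.5 to 44.4 ± 18.9 TPM and GTSE1 from 38.4 ± 0.947 to 10.4 ± 2.82 TPM. Of 33 genes of S phase and DNA replication 9 fell and 24 fell adjusted over the list alone. They included the helicase subunits MCM7 (518 ± 7.08 to 210 ± 18.0 TPM) and MCM6 (114 ± 3.42 to 51.9 ± 11.9 TPM) and the ribonucleotide reductase subunit RRM2 (178 ± 15.7 to 75.4 ± 8.24 TPM).

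Cholesterol synthesis genes of PC3 were higher as well: 5 of 24 rose and 14 rose adjusted over the list alone (median log2 change 0.60). HMGCS1 rose from 59.3 ± 11.1 to 166 ± 19.9 TPM, SQLE, the squalene epoxidase, from 133 ± 6.50 to 311 ± 25.8 TPM and CYP51A1 from 127 ± 26.0 to 260 ± 18.0 TPM. Of 15 fatty acid synthesis genes 1 rose, ACSS2 (55.4 ± 13.6 to 142 ± 17.5 TPM), and 3 rose adjusted over the list alone. Of 25 NRF2 targets 4 rose and 7 rose adjusted over the list alone. Among the 4 were HMOX1 (92.5 ± 5.04 to 277 ± 8.74 TPM), FTH1 and AKR1C1, an aldo-keto reductase that shares sequence with its family members and is uncertain for that reason. Of 48 lysosomal genes 3 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone. NEU1 and the protease gene CTSD (364 ± 4.40 to 649 ± 67.8 TPM) rose and CTSC fell (153 ± 10.3 to 78.8 ± 2 TPM). Of 38 autophagy genes 5 rose, and 5 rose adjusted over the list alone. They included the kinase ULK1, WIPI1 and GABARAPL1 (25.8 ± 1.06 to 71.4 ± 14.2 TPM). Of 21 genes of class I antigen presentation 3 rose and 6 rose adjusted over the list alone. The 3 were CALR (2113 ± 25.4 to 5937 ± 97.3 TPM), CANX and PDIA3 (179 ± 5.76 to 461 ± 44.1 TPM), which are general folding factors of the endoplasmic reticulum. Of 21 heat shock genes 3 fell, HSP90AA1 (3222 ± 169 to 1816 ± 103 TPM), HSP90AB1 and HSPE1, and 1 rose and 10 fell adjusted over the list alone.

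Of 36 interferon-stimulated genes in PC3 only IFIT3, an antiviral effector, passed (11.3 ± 2.36 to 43.0 ± 7.05 TPM; adjusted p = 0.0152), also adjusted over the list alone. ISG15 stood at 257 ± 19.7 and 373 ± 81.1 TPM (adjusted p = 0.752) and IFIT1 at 4.29 ± 0.803 and 5.87 ± 0.743 TPM. CCL5 and CXCL10 were above 0 in only 1 PC3 library each (2.42 TPM in DMSO and 2.47 TPM in GNS561). Of 24 NF-kB targets CXCL1, a neutrophil chemokine, fell from 6450 ± 474 to 2159 ± 105 TPM (adjusted p = 0.0472), and 2 fell adjusted over the list alone. SURF4, a cargo receptor between endoplasmic reticulum and Golgi, was the 1 of 16 cGAS-STING pathway components that rose (177 ± 4.48 to 296 ± 19.2 TPM), with 2 rising adjusted over the list alone. TBK1 (49.1 ± 8.16 and 38.4 ± 2.04 TPM, adjusted p = 0.682), IRF3 (67.8 ± 6.46 and 58.8 ± 4.21 TPM, 0.794) and PPT1 (170 ± 31.4 and 136 ± 19.3 TPM, 0.609) did not pass. CGAS and STING1 were not analysed here in the human lines. The other large rises were CRIP1, S100P (20.8 ± 8.29 to 172 ± 71.6 TPM), L1CAM, an adhesion molecule (7.52 ± 2.59 to 56.9 ± 7.61 TPM), DEFB103B, which has a near-identical copy and is uncertain, and AKR1C4. FAM83D, a spindle protein, fell from 111 ± 11.2 to 23.4 ± 3.81 TPM. SNORD22, SNORA13, SPANXC and KRTAP20-2 fell on 6, 3, 3 and 3 reads and did not pass in voom.

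In PC3 limma called 284 of 12030 genes, 143 higher and 141 lower, with 932 higher and 1048 lower in voom. With all 10 libraries it called 4, AGR2, HSP90B1 and HSPA5 higher and SNORA13 lower (1 higher and 1 lower with median-ratio scaling, 3 higher and 0 lower with quantile scaling). Of 27 lists 14 passed camera, and 7 held with an estimated correlation. These were G2/M and mitosis (adjusted p = 1.38e-36 and 0.0134), S phase (3.09e-19 and 0.0179) and the unfolded protein response (5.35e-20 and 0.0134). The others were integrated stress response (5.35e-20 and 0.0237), cholesterol synthesis (1.47e-12 and 0.0237), NRF2 targets (0.000137 and 0.0262) and class I antigen presentation (0.000155 and 0.0262). Another 7 passed only with the preset one. They were heat shock (1.07e-06; adjusted p = 0.0605 with an estimated correlation), lysosomal (0.000125; adjusted p = 0.169 with an estimated correlation), autophagy (0.000255; adjusted p = 0.116 with an estimated correlation). Also among them were epithelial (0.00392; adjusted p = 0.0765 with an estimated correlation), hypoxia (0.0169; adjusted p = 0.325 with an estimated correlation), vacuolar ATPase (0.0325; adjusted p = 0.116 with an estimated correlation) and fatty acid synthesis (0.0456; adjusted p = 0.310 with an estimated correlation). The count of genes moved to 8 and 10 without PC3 DMSO replicates 1 and 2, to 86 and 82 without PC3 GNS561 replicates 1 and 3, to 72 without a variance trend and to 505 with PC3 fitted alone. The fatty acid and vacuolar ATPase lists did not pass in voom, nor the epithelial list at a pseudocount of 0.1. GNS561 replicate 2, the shallowest PC3 library, stood apart from replicates 1 and 3 in mean log2 value above DMSO for lysosomal (0.04 against 0.37 and 0.38), autophagy (0.07 against 0.36 and 0.36) and hypoxia genes (-0.02 against 0.35 and 0.34). It was also apart for epithelial (0.82 against 0.42 and 0.49), fibroblast (-0.70 against 0.31 and 0.22) and leukocyte markers (0.63 against -0.13 and -0.16). With all 10 libraries 12 lists passed in PC3, and 4 held with an estimated correlation.

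The design also implies a test of whether the responses of A1847 and PC3 differed. In the 9 libraries 6 genes differed. AGR2 was listed at 0 in every A1847 library and rose in PC3 (difference of log2 changes -4.96, adjusted p = 0.00858 by limma). HSP90B1 rose in both lines and by more in PC3 (-1.25, adjusted p = 0.0328), and HSPA5 was the sixth. JUP, the junction protein plakoglobin, stood at 95.3 ± 0.228 and 62.0 ± 6.36 TPM in A1847 and at 43.6 ± 3.43 and 114 ± 7.20 TPM in PC3 (-1.98, adjusted p = 0.0476). S100A10, a partner of annexin A2, stood at 2310 ± 229 and 1412 ± 231 TPM in A1847 and 3061 ± 59.0 and 5331 ± 207 TPM in PC3 (-1.52, adjusted p = 0.0381). G0S2, an inhibitor of triglyceride breakdown, stood at 41.8 ± 3.91 and 122 ± 2.76 TPM in A1847 and 518 ± 34.8 and 298 ± 63.1 TPM in PC3 (2.34, adjusted p = 0.0476).

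Of the lists, 8 differed between A1847 and PC3 by camera. Changes were higher in A1847 for G2/M and mitosis and for S phase (adjusted p = 2.25e-11 each, with 8 members each adjusted over the list alone). The same held for NF-kB targets (5.15e-07, 9 members), cholesterol synthesis (1.07e-06, 9 members) and fatty acid synthesis (3.42e-05, 7 members). They were lower in A1847 for epithelial markers (1.08e-06, 3 members; in A1847 lower in GNS561 replicate 1 only), the unfolded protein response (0.000234, 3 members, and HSP90B1 and HSPA5 over all genes) and class I antigen presentation (0.0189, 3 members). With an estimated correlation none of the 8 passed (adjusted p = 0.0805 with an estimated correlation for S phase and epithelial markers and 0.0977 for the other 6). With all 10 libraries 0 genes and 4 lists passed, 2 upward and 2 downward, and none of them with an estimated correlation. The count of 6 moved to 1 with median-ratio scaling (0 higher, 1 lower), without a variance trend or without a filter and to 318 in voom (213 higher, 105 lower). It was 0 without any 1 of A1847 DMSO replicates 1 and 2, PC3 DMSO replicates 1 and 2 and PC3 GNS561 replicates 1 and 3. It was 2 without A1847 GNS561 replicate 1 or PC3 GNS561 replicate 2, and 355 without A1847 GNS561 replicate 2. The median of all genes lay at 0.154 and moved to -0.023 with median-ratio scaling.

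In the mouse line, labelled as a p53 knockout, Trp53 was read first. It stood at 50.5, 60.3 and 56.3 TPM in DMSO and 71.5, 87.3 and 79.6 TPM in GNS561 (adjusted p = 0.131). Since a knockout can leave a transcript, a pseudogene may share its reads (not tested) and no wild-type library was used here, this checks nothing about the label. Of 26 genes of cholesterol synthesis 19 rose and 22 rose adjusted over the list alone (median log2 change 1.70). Hmgcs1 rose from 30.7 ± 10.2 to 209 ± 33.8 TPM (SD, n = 3 and 3; adjusted p = 0.00274 by limma). Idi1 rose from 31.9 ± 12.1 to 180 ± 17.4 TPM. Of 15 fatty acid synthesis genes 7 rose and 9 rose adjusted over the list alone. They included Fasn, the fatty acid synthase (69.1 ± 25.2 to 223 ± 3.26 TPM), Elovl6 and Acly. Of 16 NF-kB targets, cytokines and chemokines 7 rose and 12 rose adjusted over the list alone (median log2 change 1.88). The chemokine gene Cxcl2 rose from 3.16 ± 5.48 to 58.1 ± 5.54 TPM, Relb, an NF-kB subunit, from 4.89 ± 4.53 to 36.5 ± 12.9 TPM and Nfkbie from 0.860 ± 1.49 to 12.7 ± 6.49 TPM. DMSO replicate 3 moved with these lists. Its mean NF-kB value stood 1.07 log2 units above the DMSO mean, against -0.49 and -0.58 in the other DMSO libraries and 1.98 to 2.27 in the treated ones, and its cholesterol synthesis value 0.46, against -0.29 and -0.16.

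Of 23 interferon-stimulated genes in the mouse line 1 rose, Isg15, a ubiquitin-like modifier (28.6 ± 18.9 to 92.5 ± 21.6 TPM; adjusted p = 0.0460), and 6 rose adjusted over the list alone (median log2 change 0.61). Other interferon and STING genes did not pass over all genes. Cxcl10 stood at 0, 0 and 3.49 TPM in DMSO and 15.7, 10.5 and 8.41 TPM in GNS561 (adjusted p = 0.0538, 0.00435 in voom). Ccl5 stood at 5.45 ± 9.44 and 34.1 ± 4.71 TPM (0.0784, 0.00614 in voom), Ifit1 at 0.951 ± 0.825 and 15.3 ± 11.5 TPM (0.112, 0.00423 in voom). Tbk1 stood at 43.6 ± 2.57 and 65.9 ± 9.67 TPM (0.117), Sting1 at 33.0 ± 5.69 and 20.9 ± 7.35 TPM (0.240) and Cgas at 8.41 ± 3.97 and 11.1 ± 1.33 TPM (0.581). Ifnb1 was listed at 0 in all 6 libraries, and Ppt1 stood at 94.1 ± 29.5 and 87.8 ± 15.1 TPM (0.907) and Irf3 at 36.1 ± 9.35 and 25.3 ± 5.43 TPM (0.352). Of 17 genes of class I antigen presentation 2 rose, Tapbp (77.7 ± 20.1 to 213 ± 38.2 TPM), which loads peptides, and B2m, the invariant light chain (2706 ± 189 to 3908 ± 351 TPM), and 5 rose adjusted over the list alone. Other large rises were Cxcl5 (35.8 ± 25.8 to 309 ± 48.3 TPM), a neutrophil chemokine, C3, a complement component, and Bcl6.

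Of 31 integrated stress response targets in the mouse line 12 fell, and 1 rose and 16 fell adjusted over the list alone (median log2 change -0.52). Trib3 fell from 162 ± 15 to 56.3 ± 20.6 TPM, Cth from 147 ± 9.03 to 45.0 ± 13.9 TPM and Psph, an enzyme of serine synthesis, from 94.2 ± 3.37 to 32.0 ± 14.3 TPM. Of 23 unfolded protein response genes 4 fell and 7 fell adjusted over the list alone. They included the transcription factor Xbp1 (294 ± 11.6 to 128 ± 21.0 TPM), Herpud1 and Hspa5 (782 ± 81.5 to 537 ± 53.6 TPM; adjusted p = 0.0407). Of 35 genes of G2/M and mitosis 5 fell and 23 fell adjusted over the list alone. Among the 5 were Cdc20 (184 ± 11.8 to 92.4 ± 16.6 TPM), Ccnb2 and Pttg1. Of 19 heat shock genes 5 rose, and 6 rose and 2 fell adjusted over the list alone. Hspa1b (73.6 ± 15.6 to 176 ± 20.6 TPM), Hspa1a and Hspa4l were among those that rose. Of 47 lysosomal genes 4 rose, and 11 rose and 3 fell adjusted over the list alone (Ctsd, Gpnmb and Npc2 rose). Of 38 autophagy genes 2 rose, Sqstm1 (611 ± 152 to 1487 ± 156 TPM) and Atg9b, with 6 higher and 1 lower adjusted over the list alone. Of 22 NRF2 targets 3 rose, Srxn1 (58.0 ± 5.58 to 143 ± 19.8 TPM), Pgd and Txnrd1, with 6 higher and 1 lower adjusted over the list alone. Cps1, a urea cycle enzyme, fell from 23.9 ± 2.79 to 1.40 ± 1.21 TPM and Sycp2l from 6.14 ± 2.15 TPM to a value listed at 0. The other large calls, Snord83b and H2bc13 upward and n-R5s107, H2ac10, Cbx3-ps1 and Psmb6-ps downward, rested on 3 to 6 reads each and did not pass in voom.

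In MyC-CaP;p53KO limma called 326 of 11040 genes, 182 higher and 144 lower, and voom 709 higher and 690 lower. By fry 18 of 26 lists passed. By camera 15 passed, and with an estimated correlation only G2/M and mitosis held (adjusted p = 2.40e-14 and 0.0200). The others were cholesterol synthesis (1.64e-24; adjusted p = 0.0912 with an estimated correlation), NF-kB targets (8.78e-12; adjusted p = 0.154 with an estimated correlation), integrated stress response (8.09e-10) and fatty acid synthesis (2.87e-08; each with adjusted p = 0.0844 with an estimated correlation). Next came the unfolded protein response (2.71e-05; adjusted p = 0.154 with an estimated correlation), interferon-stimulated genes (0.000735; adjusted p = 0.0879 with an estimated correlation) and lysosomal genes (0.00167; adjusted p = 0.0844 with an estimated correlation). The rest were NRF2 targets (0.00289; adjusted p = 0.0879 with an estimated correlation), heat shock (0.00408; adjusted p = 0.204 with an estimated correlation), autophagy (0.00509; adjusted p = 0.154 with an estimated correlation), class I antigen presentation (0.0106; adjusted p = 0.109 with an estimated correlation) and the hypoxia, immediate early and iron lists. The count moved to 71 and 64 without DMSO replicates 1 and 2, to 271 (185 higher, 86 lower) without DMSO replicate 3, to 148, 172 and 174 without GNS561 replicates 1, 2 and 3, to 217 without a filter and to 12 without a variance trend. Symbols of pseudogenes held 24.5 to 25.2% of the mouse TPM in DMSO and 26.5 to 28.0% in GNS561, so genes with pseudogene copies are uncertain. Since TPM are shares, a rise there lowers other genes. The median change of all mouse genes lay at -0.011.

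**Figure D2:**
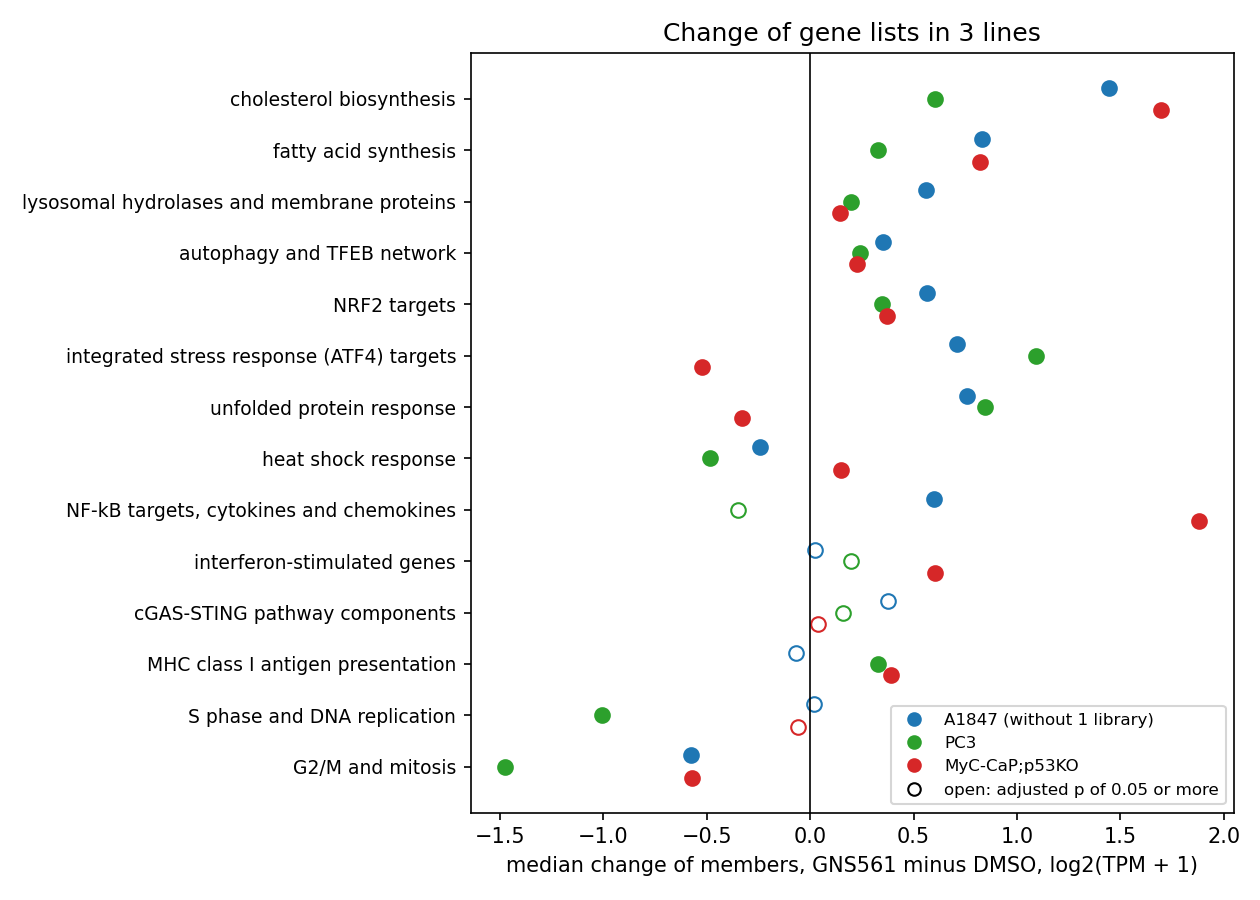
Median change of the members of 14 gene lists, GNS561 minus DMSO on the log2(TPM + 1) scale (x axis), in A1847 without the library labelled GNS561 replicate 3, in PC3 and in MyC-CaP;p53KO; open circles mark an adjusted p of 0.05 or more by camera with a preset correlation. Cholesterol synthesis lies to the right in each line (1.45, 0.60 and 1.70), and integrated stress response targets lie to the right in the human lines (0.71 and 1.09) and to the left in the mouse line (-0.52).

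The last comparison asked which genes changed in the same direction in all 3 lines, over 8025 symbols tested in each. HMGCS1, SQLE, ACAT2 and FDFT1, enzymes of cholesterol synthesis, SQSTM1, and BHLHE40, a transcriptional repressor, rose in all 3, and CDC20 fell. These 6 and 1 compare with 0.0141 and 0.0026 for independent lists. A1847 and PC3 shared a fit and so a spread estimate per gene. Their calls are therefore linked even without a common response, and independence is too low a bar wherever both enter. HMGCS1 rose by 2.24, 1.48 and 2.76 on the log2(TPM + 1) scale in A1847, PC3 and MyC-CaP;p53KO, SQSTM1 by 1.90, 1.17 and 1.30, and CDC20 fell by 1.06, 1.40 and 1.00. Among pairs of lines, 28 genes rose in A1847 and PC3 (0.8 by independence), 18 in A1847 and the mouse line (1.0) and 10 in PC3 and the mouse line (1.99). In the same order 5, 1 and 10 fell (0.22, 0.17 and 1.51). Calls in opposite directions numbered 1, 3 and 10 (14, 49 and 128 in voom), and their values by independence were not computed. An excess over independence can also reflect which genes are callable, so it does not by itself show a common response. With all 10 human libraries the count over the 3 lines was 0, since no gene passed in A1847, and voom on the 9 gave 35 higher and 46 lower (1.71 and 1.89 by independence). The count of 7 was 0 without a variance trend and 0 with each human line fitted alone. It was 0 without PC3 DMSO replicate 1 or 2, 4 without A1847 DMSO replicate 2, and 11 without A1847 GNS561 replicate 2. It was 3 without PC3 GNS561 replicate 1 or 3 and without MyC-CaP;p53KO DMSO replicate 1 or 2 or GNS561 replicate 1.

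**Figure D3:**
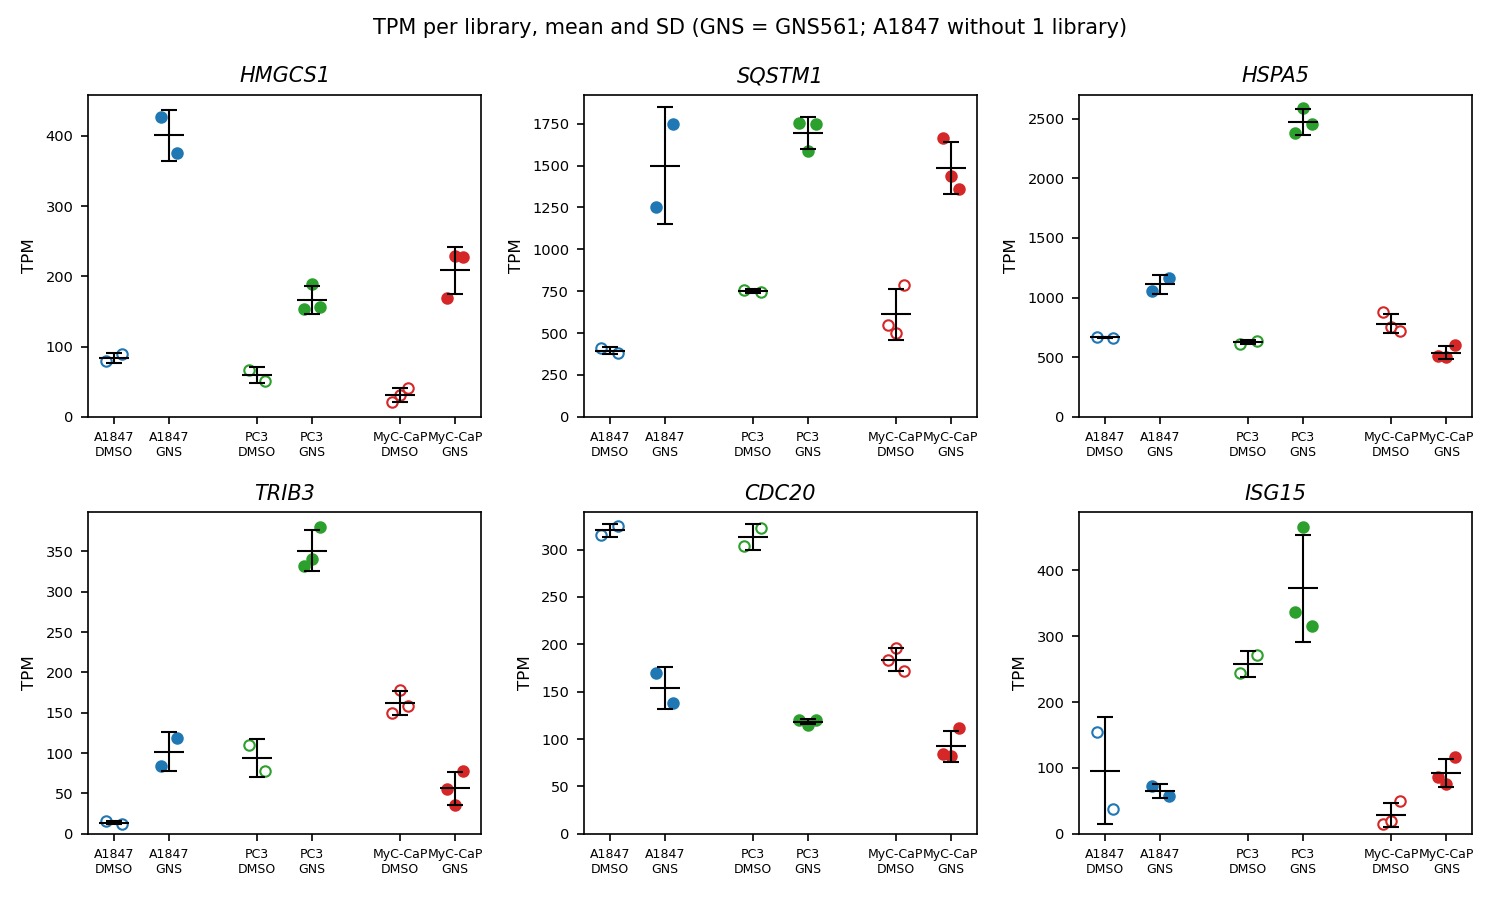
TPM of 6 genes in each library (points; open, DMSO; filled, GNS561), with the group mean and SD (bars), in A1847 without the library labelled GNS561 replicate 3, PC3 and MyC-CaP;p53KO. HMGCS1 and SQSTM1 lie higher and CDC20 lower with GNS561 in each line, and TRIB3 and HSPA5 lie higher in the human lines and lower in the mouse line.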

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

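The differences between A1847 and PC3 come from a planned contrast, read on 9 human libraries, a choice made after the result was seen, as were the tests of the doubted library except that for mixed A1847 RNA.

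Genes whose response differed between A1847 and PC3 by the contrast of both changes (A1847 minus PC3, log2) included AGR2 (-4.96), JUP (-1.98), S100A10 (-1.52), HSP90B1 (-1.25) and G0S2 (2.34). HSPA5 also passed, with a lower change in A1847, but fell outside the rule for named genes. Lists that differed by camera had median differences of 1.20 for NF-kB targets, 1.01 for S phase, 0.97 for G2/M and mitosis, 0.82 for fatty acid synthesis, 0.67 for cholesterol synthesis, -0.59 for epithelial markers, -0.31 for the unfolded protein response and -0.0227 for class I antigen presentation, and none of these held with an estimated correlation. In 3 lists the human lines moved opposite to the mouse line, a difference that was not tested. Integrated stress response targets had median changes of 0.71 in A1847 and 1.09 in PC3 against -0.52 in MyC-CaP;p53KO, unfolded protein response genes of 0.76 and 0.85 against -0.33, and heat shock genes of -0.24 and -0.48 against 0.15. With an estimated correlation the mouse changes did not pass (adjusted p = 0.0844, 0.154 and 0.204), nor integrated stress response targets in A1847 (0.0735) or heat shock genes in A1847 (0.108) and PC3 (0.0605).

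The library labelled A1847 GNS561 replicate 3 stood apart from the other A1847 libraries. Shallow sequencing was argued against by its 999644 recovered reads, since an A1847 library of 186586 reads correlated above 0.9 with the rest. A response to GNS561 was argued against by the other 2 treated libraries, which correlated with DMSO at 0.922 or more while it reached 0.759. A mixture holding 5% or more A1847 RNA was argued against by 121 genes abundant in A1847 and near 0 in mouse, whose median level in it was 0.0% of that in A1847 (81 had 0 reads), although their summed TPM was 12.02% of that level. That sum was led by MYL9 (876 TPM, against a mean of 315 in A1847), EDARADD (808 against 617) and TAF9 (577 against 224), each above its A1847 mean. Some single members had been seen before the test for mixed A1847 RNA was written. Mouse RNA read on the human gene table may account for it, since its lowest correlation with a mouse library was 0.865 and its highest with another human library 0.76. Whether it is a wrong label or a sample from outside stays open, and no mouse library was seen out of place (each correlated at 0.957 or more with the others). The doubted library correlated at 0.875 to 0.878 with the mouse DMSO libraries and at 0.865 to 0.871 with the treated ones, and its treatment was not tested.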

How the results depend on the processing

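Of the alternatives, voom on recovered reads and the repeats on 9 human libraries were chosen after the result was seen, and the others were planned. With 10 human libraries the A1847 count (0) was 1 without a filter and 0 to 97 leaving out each library. The PC3 count (4) was 7 without a filter, 2 with median-ratio scaling, 0 with the replicate block, 505 with PC3 alone and 0 to 284 leaving out each library. The count for the difference (0) was 1 at a pseudocount of 5, with the 5 TPM filter, with median-ratio scaling and without a trend, and 0 to 11 leaving out each library. With 9 libraries the A1847 count (93) was 57 with median-ratio scaling, 33 without a trend, 0 with the block, 627 in voom, 2 alone and 19 to 1023 leaving out each library. The PC3 count (284) was 72 without a trend, 3 with the block, 1980 in voom, 505 alone, 179 with an absolute log2 change of at least 1 and 8 to 316 leaving out each library. The difference (6) was 1 without a filter, with median-ratio scaling and without a trend, 0 with the block, 318 in voom and 0 to 355 leaving out each library. The mouse count (326) was 217 without a filter, 12 without a trend, 115 with the block, 1399 in voom, 162 with an absolute log2 change of at least 1 and 64 to 271 leaving out each library. Genes shared by all 3 lines (7 on 9 libraries) were 0 without a trend, with the block and with each line alone, 81 in voom and 0 to 11 leaving out each library, and with 10 libraries 0 to 7. Of list calls with 10 human libraries and the mouse line (31), 6 held with an estimated correlation and 30 to 41 were made leaving out each library; with 9 (41), 12 and 38 to 43. By fry 23 and 41 list calls were made. With 10 libraries fry passed 1 list in A1847 and 4 in PC3, where camera passed 4 and 12. With 9 libraries fry passed 12 and 11, where camera passed 12 and 14. In the mouse line fry passed 18 and camera 15, and for the difference on 9 libraries 7 and 8. The median change of the interferon-stimulated genes, A1847, with 10 libraries (-0.95, not past the threshold) was -0.98 with median-ratio and -0.77 with quantile scaling and -1.29 with A1847 alone, each past the threshold with the preset correlation (without these changes adjusted p = 0.908 with an estimated correlation, which was not repeated under them). It was -1.71 to 0.0214 leaving out each library. The difference of cholesterol synthesis on 10 libraries (-0.61) reversed to 0.71 with the block and lay at -1.43 to 0.67 leaving out each library, the high end without the library labelled A1847 GNS561 replicate 3. The block takes that library out of the treatment change as well. Of the 41 list calls on 9 libraries and the mouse line, 39 to 41 passed in each of the pseudocount, filter, scaling, variance, block and voom settings, 36 in every leave-one-out, and 0 changed direction; of 151 calls of named genes 129 to 149 passed in these settings except without a trend (40) and with the block (33), 35 in every leave-one-out, and 0 changed direction. With each human line fitted alone, which applies to neither the difference nor the mouse line, 25 list calls and 52 calls of named genes passed, and 1 of the 93 genes of A1847 was still called. The block uses numbers that samples share without being paired (correlations of same-numbered deviations lay within 0.05 of 0) and leaves few degrees of freedom. Human replicate 3 exists only with GNS561, so the block gives it a term of its own and removes it from the treatment change. With the block on 10 libraries the median change of all A1847 genes was 0.069, against 0.07 on 9 libraries without the block. The cause of the other shifts was not tested, and read numbers limit low genes.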

Other observations

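Of the tests here, those of few reads, of shallow sequencing, of held-out libraries and of the splits were chosen after the result was seen, and that of mixed RNA before its medians were computed but after values of single genes had been seen.

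Of 9 iron handling genes 2 rose in A1847 and 2 in PC3, both times the ferritin genes FTH1 and FTL (2 adjusted over the list alone in each; the list did not pass in PC3, adjusted p = 0.221 by limma's camera). In MyC-CaP;p53KO 1 rose, the transferrin receptor Tfrc (201 ± 41.6 to 363 ± 21.6 TPM). There 4 rose adjusted over the list alone (0.00353; adjusted p = 0.154 with an estimated correlation). NDRG1, a gene raised by low oxygen, rose in PC3 from 94.1 ± 21.4 to 499 ± 13.1 TPM and in A1847 from 92.2 ± 6.35 to 208 ± 7.65 TPM. In A1847 LDHA of the same list fell and ENO2 rose (157 ± 8.43 to 310 ± 1.90 TPM). The list passed in PC3 (0.0169; adjusted p = 0.325 with an estimated correlation), where GNS561 replicate 2 lay within the DMSO range (-0.02), and in the mouse line (0.000787; adjusted p = 0.0844 with an estimated correlation), where Slc2a1, a glucose transporter, rose from 78.1 ± 13.7 to 150 ± 29.4 TPM. Of 22 mouse immediate early genes 5 rose, and 9 rose and 1 fell adjusted over the list alone (0.000787; adjusted p = 0.109 with an estimated correlation). Among them were Dusp1 (21.8 ± 7.88 to 70.9 ± 26.0 TPM), Maff and Fosl1. In PC3 JUNB rose and FOSL1 fell (963 ± 73.0 to 569 ± 24.6 TPM). Of the p53 targets CDKN1A rose in A1847 (22 ± 2.68 to 64.7 ± 0.885 TPM), and in the mouse line Trp53inp1 (9.38 ± 2.93 to 41.4 ± 1.22 TPM) and Plk3 rose and Fdxr fell.

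Lists that did not pass, in A1847, PC3 and MyC-CaP;p53KO in that order, had adjusted p of 0.372, 0.746 and 0.406 for p53 targets, 0.195, 0.102 and 0.107 for checkpoint ligands, 0.294, 0.253 and 0.482 for cGAS-STING components, 0.932, 0.836 and 0.429 for LXR targets, 0.932, 0.342 and 0.747 for metallothioneins, 0.195, 0.967 and 0.122 for depalmitoylating enzymes, 0.298, 0.836 and 0.452 for fibroblast markers and 0.638, 0.302 and 0.406 for leukocyte markers (5, 5 and 2 members tested). Endothelial markers had 0.953 and 0.989 in the human lines and none was tested in mouse. In A1847 the immediate early (0.0510), vacuolar ATPase (0.0714), class I antigen presentation (0.294, with 2 members higher, CALR and CANX, and a median of -0.07 against a mean of 0.07), hypoxia (0.294), S phase (0.372) and interferon-stimulated lists (0.953) did not pass, nor in PC3 the NF-kB (0.0852), interferon-stimulated (0.102) and immediate early lists (0.170), nor in the mouse line the vacuolar ATPase (0.0610), S phase (0.634, with E2f1 higher) and epithelial lists (0.998, with Cldn3 higher and a median above 0 while the test pointed down). Signs also differed for metallothioneins in A1847 (median 0.33, mean -0.13), iron handling in PC3 (median -0.05, mean 0.09), S phase in A1847 (median 0.02, test downward) and endothelial markers in PC3 (median -0.06, test upward).

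MyC-CaP;p53KO DMSO replicate 3 lay between the other DMSO libraries and the treated ones, and shallow sequencing was argued against by its reads, 90.4% of those of the deeper other DMSO library. Among genes called without it, the 86 that fell were shifted toward the treated mean by a median of 26.7% (21.7 to 32.1) and the 185 that rose by 25.3% (22 to 28.9), with 71 and 175 of them shifted that way. The same procedure gave -9.2 to 4% for replicates 1 and 2, but there replicate 3 was part of the control mean. On genes chosen with DMSO replicate 1 or 2 and the treated libraries only, the other of that pair shifted by 20 to 49.6% and replicate 3 by at least 11 percentage points more, and in 1 of 4 comparisons the intervals overlapped (50 to 60.7 for replicate 3 against 40.8 to 50.8). Regression toward the treated mean is thus not excluded, and mixing with RNA of treated cells and a culture partly in the treated state stay open too.

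In the other splits of the 6 mouse libraries into 3 and 3, the highest count was 3 genes against 326 in the real split, which was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05.

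Calls on very few reads were the other pattern. Of 21 calls resting on under 20 recovered reads over the 3 lines, 76.2% did not pass in voom, against 1.5% of 657 calls with at least 100 reads. Voom used the same read numbers, and a gene of few reads can hardly pass it, so this loss cannot show why limma called these genes. Single reads of short genes may account for calls such as SNORD42A, SNORA13 and Snord83b, but gene length was not tested. Recovered read numbers are lower bounds, which weighs most on genes seen in few libraries. No biological explanation was tested for this pattern.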
